A study of Homo sapiens with 8 samples.

How the data were processed

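H3K27ac, the acetylation of lysine 27 on histone H3 that marks active promoters and enhancers, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in SKOV3 cells, an established human ovarian cancer cell line. The cells were kept in detached culture for 12 h, per the labels. They carried either the empty pLKO vector (shControl) or a short hairpin RNA against SAT1 (shSAT1), and each group had 3 libraries that the labels number as biological replicates. The 2 input samples were not used here. Chromatin was cut by enzymatic digestion, per the labels' protocols. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be partly technical.

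The processed data were 6 peak lists, called separately for each library. Bowtie2 2.5.3, MACS3 3.0.1 and ChIPseeker are named in the submitters' processing notes, together with the genome build hg38. The files themselves use the older build. Their contig names belong to hg19, and only 715 of 12745 genes (5.6%) lay within 10 kb of their position in a GRCh38.p14 gene table, which was used for names and for this check alone. All coordinates are therefore given as hg19, as the deposited files hold them. Every row of the lists was 1 bp wide and each peak number occurred once, so a row is the summit (highest point) of a called peak and the width of the peak is unknown. Between 2 and 19 peak numbers per library had no row. The deposited score of each summit behaved as a −log10 q value, with the lowest scores just above 2 in all 6 libraries; it is the authors' own value and was used only to rank or filter summits within a list. Summit positions and the distance to the nearest transcription start site were used as deposited. The annotation class and the gene of each summit are also the authors', from the nearest start site in ChIPseeker's output. A promoter is within 3 kb of a start site in this annotation.

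The lists held 22983 to 26067 summits per library and 146003 in total. They hold no read counts, no fold enrichment and no sequencing depth, so the depth is unknown and no change in signal height could be measured. A peak that is present in one list and absent from another has crossed the caller's threshold in one of them only. Positions shared exactly between any pair of libraries made up at most 4.1% of summits, so no list was a copy of another.

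The planned quantity was the number of base pairs under peaks, which 1 bp rows do not hold. After the files were seen it was replaced by the number of summits. Promoter coverage became promoter summits per gene, and region coverage became summits per stitched region, where summits at most 12.5 kb apart from the next were joined. A further quantity, all summits assigned to a gene, was added. Each was analysed as log2(summits + 1), mean-centred per library, for features with a mean of at least 3 summits per library, where the planned filter was a peak in at least 3 libraries. That filter, run as an alternative, kept 11779 genes, of which 48.2% had equal counts within both groups and so no spread for the test. The fits used limma 3.58.1 in R 4.3.3 (empirical Bayes with trend and robust settings), at a Benjamini-Hochberg adjusted p of 0.05. Fold changes are on the log2(summits + 1) scale and understate the change of features with few summits. The scripts were tested on simulated data before use. With 200 changed genes among 1870, 32.3% of genes changed 1.5-fold, 80.0% of those changed 2-fold and 93.8% of those changed 3-fold were recovered for summits per gene, with 3 false calls beside 138 true ones. For stitched regions (200 of 1612 features changed) the shares were 50.0%, 81.8% and 98.2%, with 4 false calls. For promoter summits (78 of 235 features changed) they were 45.2%, 71.4% and 94.7%, with 0 false calls. The simulated spread depended on the mean count alone, and the shares depend on how many features change. They need not hold in the real data.

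For presence and absence, each summit was given 250 bp on each side and overlapping windows of the 6 libraries were merged into regions. A region or promoter is called group-specific when all 3 libraries of one group have a summit there and none of the other group does. Because a summit of the other group can lie close by, the regions were also counted with the condition, added after seeing the data, that no summit of the other group lay within 3 kb; these are called isolated regions. The same count was made for all 10 splits of the 6 libraries into groups of 3. Similarity between libraries was the Jaccard index of the 500 bp windows. Values per library were compared with exact two-sided permutation tests, whose smallest p for 3 against 3 libraries is 0.1. Wilson intervals (95%) of shares of regions treat regions as independent and cover counting error only.

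A total of 29 gene lists (849 genes, of which 660 had a summit in any library) was fixed before the data were examined. They cover mitosis, DNA replication, DNA damage, polyamine metabolism, acetyl-CoA supply, histone acetylation, AP-1, epithelial and mesenchymal genes, adhesion, apoptosis, YAP targets, hypoxia, stress responses, antioxidants, lipid synthesis, NF-kB, interferon, autophagy, growth factor signalling, ribosomal proteins, oxidative phosphorylation, ovarian and Müllerian genes, stem cell genes and markers of 5 other cell types. Lists with at least 5 tested genes were tested with camera (inter-gene correlation 0.01) on summits per gene. List membership among group-specific promoters was tested with Fisher's exact test. Lists near group-specific regions were compared with 10000 random lists matched on the number of regions per gene, a test added after seeing the data.

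Named genes followed a rule fixed for promoter coverage before the data were examined. After the files were seen it was also applied to summits per gene. Percentiles of the score then took the place of planned percentiles of fold enrichment. The rule takes up to 12 genes per direction of largest fold among those past the test with separated groups. For promoters, where fewer than 6 passed per direction, it takes the 12 group-specific promoters per direction whose lowest-ranking library had the highest score percentile in its own list. It also takes up to 4 group-specific members per gene list, 5 regions per direction, and SAT1, JUN, FOSL1, MYC, ERBB2, CDK1, AURKA and CCNB1. Non-coding genes with LOC, LINC, MIR or SNOR symbols and antisense transcripts were not named. A few genes that the rule would name are not reported here. Genes named outside the rule are said to be chosen after their values were seen. The alternatives tried were stricter scores, equal list lengths, other window widths, promoter definitions, transformations, centring, filters, a replicate block and leaving out each library. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for the remaining steps.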

Results

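The genome-wide distribution of H3K27ac was compared between SAT1-depleted and control SKOV3 ovarian cancer cells after 12 h without attachment, to find regions where the mark differs when SAT1 is depleted. SAT1 encodes spermidine/spermine N1-acetyltransferase 1, which acetylates polyamines using acetyl-CoA. The data were 3 shControl and 3 shSAT1 lists of peak summits. The shControl lists held 22983, 24705 and 23218 summits and the shSAT1 lists 24627, 26067 and 24403. The means were 23635 ± 934 and 25032 ± 903 (SD, n = 3 each). The means differed by 1397 summits (5.91%) and the groups overlapped (exact two-sided permutation p = 0.3; 0.1 is the smallest p this design allows).

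The SAT1 promoter itself carried H3K27ac in every library, with 2 promoter summits in each of the 6, at chromosome X around position 23801591 (hg19). H3K27ac at the target promoter does not measure the amount of SAT1 transcript, so it does not check the knockdown. The promoters of JUN and FOSL1 (AP-1 subunits), MYC (a growth-promoting transcription factor), ERBB2 (a receptor tyrosine kinase) and the mitotic regulators CDK1, AURKA and CCNB1 likewise had a summit in all 6 libraries. Of 10962 genes with a promoter summit in any library, 8889 (81.1%) had it in all 6. Mitosis and spindle genes, the largest list, had 54.3 ± 1.15 members with a promoter summit in shControl and 53.0 ± 2.65 in shSAT1 (SD, n = 3; exact p = 0.7), and polyamine metabolism genes had 17.3 ± 1.53 and 17.3 ± 0.58.

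Promoters held the largest share of summits in both groups. The promoter share was 51.4 ± 0.44% of summits in shControl and 50.1 ± 0.92% in shSAT1, the intron share 25.9 ± 0.43% and 26.2 ± 0.67%, and the distal intergenic share 20.4 ± 0.41% and 21.4 ± 0.41% (SD, n = 3). For promoters and for distal sites the 3 libraries of one group lay apart from the 3 of the other, which gives the smallest exact p of 0.1 and an adjusted p of 0.35 over 7 classes. When all lists were limited to the length of the shortest, the promoter difference changed from -1.33 to 0.26 percentage points. Trimming also removes the summits of lowest score. Libraries of the same group shared more of their summits than libraries of different groups. The mean Jaccard index was 55.9% within groups and 50.05% between them, a difference of 5.84 percentage points (exact one-sided permutation p = 0.1). The ranges of 51.9 to 58.5% and 48.8 to 51.5% did not overlap.

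Genes with more acetylated sites in shSAT1 cells included HAS3, which encodes a hyaluronan synthase, HRH1, a histamine receptor, AFF1, a component of the transcription elongation machinery, and PTP4A2, a protein tyrosine phosphatase. Genes with fewer sites included SFN, which encodes 14-3-3 sigma, NRP1, a co-receptor for semaphorins and VEGF, and COL12A1, a collagen chain. Sites were assigned to the nearest start site at any distance and need not lie in the gene. Those of COL12A1 ran from 75176081 to 75915576 on chromosome 6. Among 1870 genes with a mean of at least 3 summits per library, 19 had more summits in shSAT1 and 8 had fewer (limma, adjusted p under 0.05; 184 and 170 at an unadjusted p under 0.05). Without centring the split was 36 higher and 6 lower. The filter planned for coverage, a summit in at least 3 libraries, gave 319 higher and 160 lower of 11779 genes, and 367 of these 479 had counts that were equal within both groups. The groups lay apart at 14.5% of the tested genes, against 1.7 to 6.5% in the other splits of the 6 libraries into groups of 3. HAS3 went from 7.0 ± 1.0 to 14.3 ± 0.58 summits (SD, n = 3; log2 fold change 0.86 ± 0.13 SE), HRH1 from 8.0 ± 1.0 to 16 ± 1.73 (0.83 ± 0.14) and AFF1 from 3 in every shControl library to 7 in every shSAT1 library (0.91 ± 0.12). NRP1 went from 14.7 ± 0.58 to 8.7 ± 0.58 (-0.79 ± 0.11), SFN from 7.7 ± 0.58 to 4.0 ± 0 (-0.88 ± 0.12) and COL12A1 from 12.0 ± 1.0 to 7.0 ± 1.0 (-0.79 ± 0.15). The limma adjusted p was 0.0448 for each of these 6 genes. MARK3, TM4SF20, ANAPC16, IQCD, ZNF608, RHPN2, PPFIA1 and NIFK were also higher, with log2 fold changes from 0.82 (NIFK) to 1.29 (MARK3), and KAAG1, TMEM92, IL37 and MYZAP were lower, from -0.57 (MYZAP) to -1.21 (KAAG1). A difference in summit number can come from new peaks or from a broad peak being called in more pieces, which these lists cannot separate. The calls lie just under the threshold: leaving out any one of the 6 libraries gave between 0 and 3 calls (higher and lower together). At most 1 of these was among the 27 genes called with all libraries. With the replicate number as a block, 0 genes passed in either direction. Equal list lengths gave 5 higher and 2 lower, and 5 of these 7 were among the 27. The 15 named genes lost at equal list lengths kept 75 to 101% of their log2 fold changes.

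**Figure D1:**
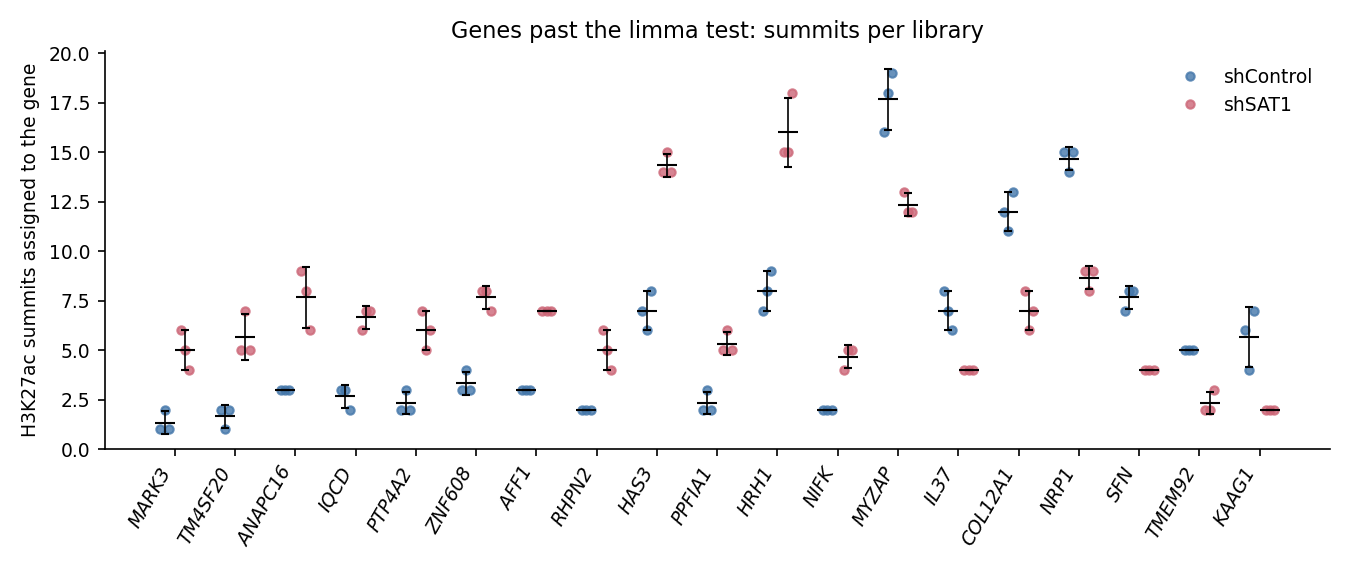
Number of H3K27ac summits assigned to each of the 19 named genes past the limma test (y axis) in each library (points; blue shControl, red shSAT1), with group mean and SD as black bars (n = 3). Genes were named only where the groups lie apart, for example 14 or 15 against 6 to 8 summits at HAS3.

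Neighbouring summits were also stitched into regions regardless of gene assignment. Of 1612 stitched regions tested, 15 had more summits in shSAT1 and 9 had fewer (limma, adjusted p under 0.05; 154 and 150 at an unadjusted p under 0.05). Of these 24 regions, 9 lay at a gene called above. Both measures count the same summits, so this overlap is not independent support. The region upstream of HAS3 (chromosome 16, 69073007 to 69112138, 39.1 kb) held 3.7 ± 0.58 summits in shControl and 10.3 ± 0.58 in shSAT1 (SD, n = 3; log2 fold change 1.22 ± 0.14 SE, limma adjusted p = 0.0289). Its summits from 69073007 to 69095682 came from shSAT1 libraries only. Their scores were low, at 4.8 to 11.2 against medians of 20.46 to 23.26 over the shSAT1 lists. Other regions with more summits were at PTP4A2 (chromosome 1, 32389154 to 32421341), SNX9, a sorting nexin (chromosome 6, 158243860 to 158261313), TSPAN15, a tetraspanin (chromosome 10, 71197271 to 71234703), TKT, the transketolase of the pentose phosphate pathway (chromosome 3, 53256332 to 53289809), and LOXL2, a lysyl oxidase (chromosome 8, 23261369 to 23278518). Regions with fewer summits included SFN (chromosome 1, 27175183 to 27192109), with 7.7 ± 0.58 against 4.0 ± 0, and NRP1 (chromosome 10, 33526638 to 33580912), with 9.7 ± 0.58 against 5.3 ± 0.58. The stitched regions named here were chosen after their values were seen. No region passed at equal list lengths or with the replicate number as a block. Without 1 library between 0 and 2 higher and 0 lower regions passed.

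**Figure D2:**
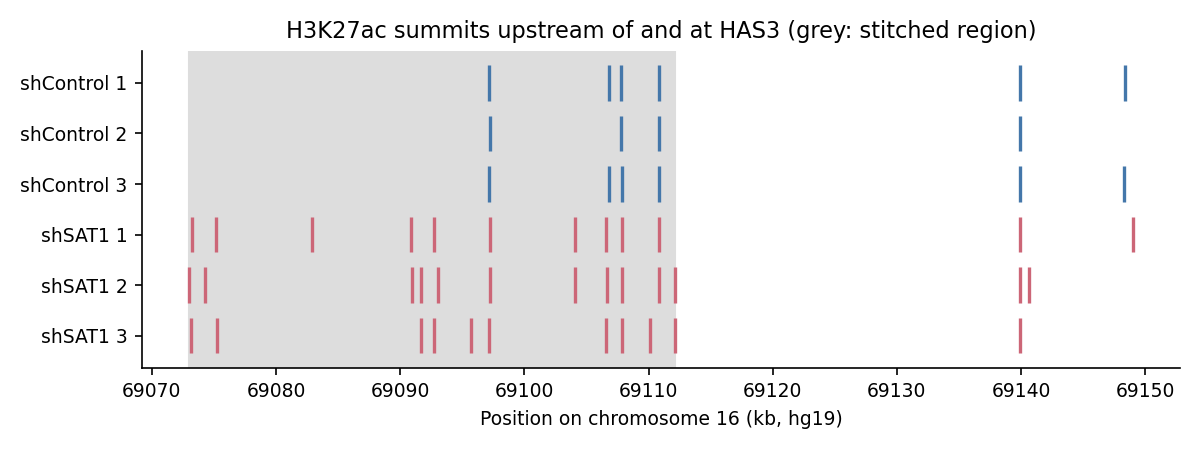
Positions of H3K27ac summits (vertical ticks) on chromosome 16 in hg19 (x axis, kb) in each of the 6 libraries (rows; blue shControl, red shSAT1), with the stitched region from 69073007 to 69112138 in grey. The shSAT1 libraries hold 10 or 11 summits in the grey region and the shControl libraries 3 or 4, while all 6 have a summit at the HAS3 start site between 69139892 and 69139915.

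Counting promoter summits alone gave no gene past the test. Of 235 genes with a mean of at least 3 promoter summits, 0 passed in either direction (limma, adjusted p under 0.05; 16 higher and 8 lower at an unadjusted p under 0.05). Lowering the minimum to a mean of 2 summits gave 9 higher and 3 lower of 901 genes.

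Sites present in one group only were more numerous in shSAT1. Merging the summits gave 39001 regions, of which 14527 (37.2%) were found in all 6 libraries, 1242 in all shSAT1 and no shControl libraries, and 578 in the reverse. Together these 1820 group-specific regions were 4.67% of all regions. Many lay close to a summit of the other group: 776 of them (42.6%) had a summit of all 3 libraries of the other group within 3 kb, against shares from 106 of 212 to 143 of 227 (63.0%) in the other splits, and 281 had one of 1 or 2 libraries. Without peak widths, a summit shifted within a broad peak cannot be told from a separate neighbouring peak. The remaining 763 isolated regions comprised 570 in shSAT1 only and 193 in shControl only, and 338 and 111 remained when no summit of the other group was allowed within 10 kb. Equal list lengths gave 1016 and 643 group-specific and 473 and 236 isolated regions. Among regions with scores at or above the median in all 3 lists, shSAT1-only and shControl-only regions were about equal in number (101 and 97), 27 and 11 of these were isolated, and 68 and 83 had all 3 libraries of the other group nearby. Group-specific regions lay away from promoters more often than regions found in all 6 libraries. The promoter share was 26.9% (95% Wilson interval 24.5 to 29.4%) of shSAT1-only and 32.0% (28.3 to 35.9%) of shControl-only regions, against 65.0% of regions in all 6, while introns took 39.4%, 40.1% and 17.3%. Their median scores were low, at 9.36 and 10.49 against 48.0 for regions in all 6 libraries. The promoter and intron shares were not compared at matched scores or in the other splits, so they need not reflect the grouping.

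**Figure D3:**
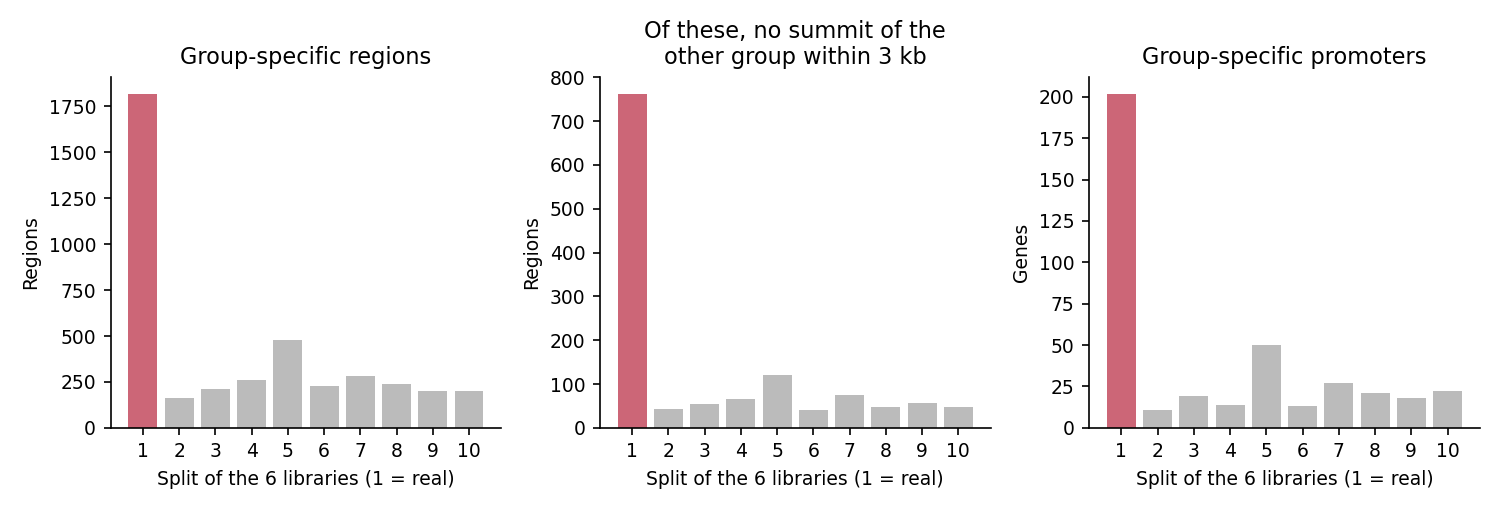
Number of group-specific regions (left), of isolated group-specific regions (middle) and of genes with a group-specific promoter summit (right) for each of the 10 splits of the 6 libraries into groups of 3 (x axis; red bar, the real split; grey bars, the other 9). The real split gives 1820 regions, 763 isolated regions and 202 promoters, and the highest other split 478, 120 and 50.

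Most group-specific regions of highest rank lay beside summits of the other group. At ATF4, a transcription factor of the stress response, the shControl summits lay upstream of the start site (region on chromosome 22, 39915638 to 39916168) and the shSAT1 summits downstream of it (39916530 to 39917041). VPS26C promoter summits lay at 21:38639123 to 38639635 in shControl and 21:38639917 to 38640427 in shSAT1, and those in an HDAC4 intron at 2:240167953 to 240168466 and 2:240168683 to 240169184. NR3C1, which encodes the glucocorticoid receptor, had an shSAT1-only region at 5:142784399 to 142784931. TRIM41 (5:180650096 to 180650640) and ABCF3 (3:183903863 to 183904385) had shControl-only promoter regions. All these had a summit of all 3 libraries of the other group within 3 kb. At MIDN, which encodes midnolin, the shControl summits at the promoter (position 1249358 of chromosome 19) and the shSAT1 summits in an intron (19:1252542 to 1253079) lay farther apart than 3 kb.

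**Figure D4:**
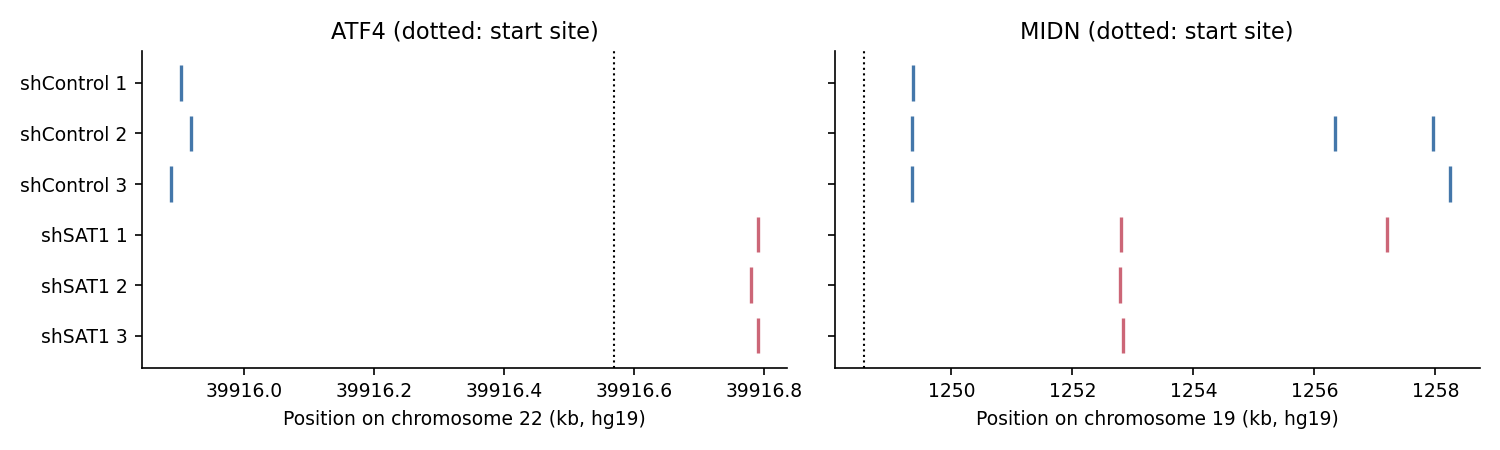
Positions of H3K27ac summits (vertical ticks) around ATF4 on chromosome 22 and MIDN on chromosome 19 in hg19 (x axes, kb) in each of the 6 libraries (rows; blue shControl, red shSAT1), with the start site dotted. All 3 libraries of a group place their summit together, with shControl upstream and shSAT1 downstream of the ATF4 start site, and at MIDN near 1249358 in shControl and near 1252792 in shSAT1.

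Among isolated regions, shSAT1-only sites of highest rank included the promoters of OAS3, an interferon-induced oligoadenylate synthetase (chromosome 12, 113376183 to 113376704), ZNF618 (chromosome 9, 116638593 to 116639189), SETMAR (chromosome 3, 4344917 to 4345434) and SLC25A30, a mitochondrial carrier (chromosome 13, 45991969 to 45992523). An intron of MAPK8IP1 (chromosome 11, 45921317 to 45921818) and a distal site near TM4SF20 (chromosome 2, 228268047 to 228268615) belonged to the same class. Isolated shControl-only sites included a site upstream of SREBF1, the sterol-responsive transcription factor (chromosome 17, 17743467 to 17744303), the promoter of TAB1, a kinase adaptor (chromosome 22, 39795767 to 39796309), and an LMNA intron, in the gene of lamin A/C (chromosome 1, 156099470 to 156100037). These isolated regions were chosen after their values were seen.

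Of the genes with a promoter summit in one group only, 136 held it in shSAT1 and 66 in shControl. Where scores lay at or above the median in all 3 lists the numbers were 20 and 20. When any summit within 3 kb of a start site was counted, whichever gene it was assigned to, the numbers were 120 and 44. Of the 202 calls, 113 shSAT1-only and 43 shControl-only promoters held under both definitions and 46 did not; among those of high score 10 and 4 held. The rule for named genes took 12 promoters per direction, and of these 9 shSAT1-only and 10 shControl-only calls ended under the second definition. Several lay at neighbouring genes, with the summit nearest to one gene in shSAT1 and to the other in shControl, as for CNPPD1 (shSAT1) and RETREG2 (shControl), VPS9D1 and ZNF276, TRMT5 and SLC38A6, TRMT2A and RANBP1, and PMS2P4 and STAG3L4. Other calls that ended included TIGD4, HIGD2A and SKA3 in shSAT1 and FASTK, PHF7, TUFM and ZNF570 in shControl. The named calls that held were OAS3, ZNF618 and CLUHP3 in shSAT1 and RPS16 and MIDN in shControl. RPS16, a ribosomal protein gene, had its shControl summit 249 bp from the start site (chromosome 19, 39926369), and all 3 shSAT1 libraries had one beyond the end of the gene, near 39922004, as had shControl 2. Among calls that held and were chosen after their values were seen, EPAS1 (HIF-2 alpha, chromosome 2, 46524613), CCNE1 (cyclin E1, chromosome 19, 30302388), TNFSF10 (the death ligand TRAIL, chromosome 3, 172241054) and ABCC3 (a drug efflux transporter, chromosome 17, 48712413) had promoter summits only in shSAT1, and EBPL, TUBA4A, PCLAF and TRIM29 only in shControl.

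The fixed gene lists differed little between the groups. By members with a promoter summit, interferon response genes had 19.0 ± 1.0 in shControl and 22.3 ± 1.15 in shSAT1 (SD, n = 3; exact p = 0.1, adjusted p = 0.58 over 29 lists). OAS3 had it in 0 and 3 libraries of the groups, and OAS2 and IFIH1, an RNA sensor, both chosen after their values were seen, in 0 and 2. Epithelial junction and keratin genes went from 17.0 ± 0 to 18.3 ± 0.58 members with EPCAM, the epithelial adhesion molecule, in shSAT1 only (chromosome 2, 47596899), where its lowest score was 2.2. The ovarian and Müllerian list went from 12.7 ± 0.58 to 14 ± 0 with the adhesion molecule BCAM (chromosome 19, 45311899) in shSAT1 only. Apoptosis and anoikis genes differed in the other direction, with 24.0 ± 0 and 22.3 ± 0.58 members. The survival gene BCL2 (chromosome 18, 60987084) was in shControl only, where its lowest score was 6.6. Cytosolic ribosomal protein genes had 37.0 ± 0 and 35.3 ± 0.58, with RPS16 as described. All 5 lists had the exact p of 0.1 and adjusted p of 0.58, against a mean of 0.4 lists with separated groups in the other splits. Counting any summit within 3 kb kept these 5 lists separated and added hypoxia and glycolysis (27 ± 0 and 28.3 ± 0.58), which includes EPAS1. The epithelial list then had 18 and 19 members in every library of the groups, and the ovarian list 13 and 14. Apoptosis and anoikis had 24 and 23, and ribosomal proteins 38 and 37. These differences match EPCAM, BCAM, BCL2 and RPS16, so for these lists the separation adds nothing beyond those genes. WWTR1, a YAP partner, was shSAT1-only by assigned gene but had a summit within 3 kb in all 6 libraries. Fisher's exact test found 0 lists enriched among group-specific promoters, and 0 lists lay near group-specific regions more often than matched random lists. The lowest p there was that of endothelial markers, a list of another cell type, with 4 shSAT1-only regions at PECAM1 and TIE1 (chosen after their values were seen) against a mean of 0.54 in random lists (permutation p = 0.0068 from 10000 random lists, adjusted p = 0.367).

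**Figure D5:**
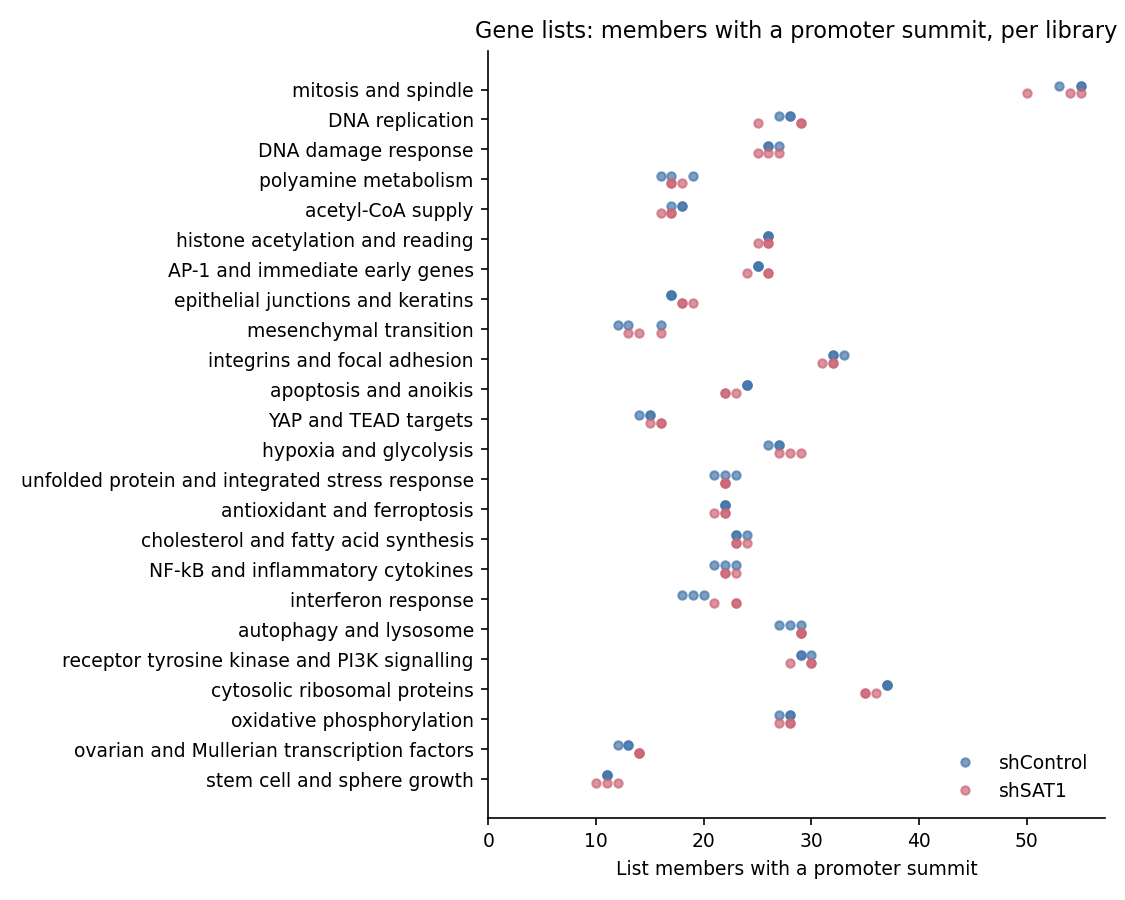
Number of members of each fixed gene list with a promoter summit (x axis) in each library (points; blue shControl, red shSAT1), for the 24 lists that are not markers of other cell types. Groups lie apart for 5 lists, such as interferon response (18 to 20 against 21 to 23), and overlap or touch for the rest.

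Across summits per gene, 0 of 16 lists passed the camera test (adjusted p under 0.05; 2 at an unadjusted p under 0.05). The mesenchymal transition list had the lowest value, with all 6 of its tested genes above 0, a median log2 fold change of 0.18 and camera adjusted p = 0.0801 (adjusted p = 0.566 with an estimated correlation). It passed only without shControl replicate 1, at a camera adjusted p of 0.0245, and ranged up to 0.458 without another library. The other list at an unadjusted p under 0.05 was apoptosis and anoikis: 8 of 9 tested genes lay above 0, with a median log2 fold change of 0.21 and camera adjusted p = 0.315. Its promoter members had differed in the other direction, but neither measure passed its test and the measures were not compared by a test. Interferon response also differed between the measures, with 1 of 6 tested genes above 0, a median of -0.16 and camera adjusted p = 0.911. Of the members of the mesenchymal transition list, 0 passed over all genes and 2 when adjusted over the list alone: TGFBI, a secreted matrix protein, with 5.3 ± 1.53 and 13.0 ± 3.0 summits (SD, n = 3), and LOXL2, with 2.0 ± 0 and 4.3 ± 0.58. Over the 16 lists 0 members passed over all genes and 7 when adjusted over the list alone. The members named here were chosen after their values were seen. The 7 also included TRAF1, an NF-kB target (2.3 ± 0.58 and 4.7 ± 0.58), XIAP, an inhibitor of apoptosis (3.3 ± 1.15 and 7.7 ± 1.53), TNFAIP3, an NF-kB inhibitor (14 ± 3.0 and 7.3 ± 1.53), and NFKB2 (5.0 ± 0 and 3.3 ± 0.58). Markers of other cell types had promoter summits at few members in both groups: 4 neuron, 1 blood and 1 liver marker in every library, 0.67 ± 1.15 and 0.67 ± 0.58 fibroblast markers, and 1.67 ± 0.58 and 2.0 ± 0 endothelial markers, where PECAM1 was found in shSAT1 only and CDH5, chosen after its values were seen, in 2 shControl libraries only.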

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

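The windows of 100, 500 and 1000 bp on each side of a summit, the restriction to high scores, the lists near group-specific regions, the 3 kb and 10 kb distances, the main-chromosome count, the summit transformations, the filters on mean summits, promoters of high score, the count of any summit within 3 kb, the stitching distance and all settings for summits per gene were chosen after seeing the data. The planned pseudocounts of 50 and 1000 bp were not run, because the lists hold no peak widths. Nothing here can show a change in signal height, since the depth of the libraries is unknown.

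The shSAT1-only regions outnumbered the shControl-only ones under the settings run, but only by 101 to 97 where scores lay at or above the median in all 3 lists. Among the regions of that subset with all 3 libraries of the other group within 3 kb, they were fewer, 68 against 83. The counts also moved by over 1.5 times with windows of 1000 bp on each side of a summit (666 and 257), with no summit of the other group within 3 kb (570 and 193) and within 10 kb (338 and 111). Leaving out 1 library loosens the definition and gave 1487 to 1967 shSAT1-only and 787 to 1123 shControl-only regions, 157 to 229 and 80 to 103 promoters (20 and 20 at scores at or above the median in all 3 lists, with all libraries), and 3 to 6 lists higher and 2 to 3 lower in promoter members. At equal list lengths the promoter share changed sign to 0.26 and the intron share to -0.76 percentage points; the cause was not tested. Summits per library and similarity between libraries kept their direction, and their exact tests cannot reach a p under 0.05 with so few libraries. The Fisher and random-list tests found 0 lists in each setting run. For camera, 0 to 1 lists passed with 1 library left out, the 1 being the mesenchymal transition list without shControl replicate 1, and 0 under the other settings.

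The limma counts depended on the setting, and the cause was not tested except where fewer libraries or summits entered. Summits per gene (19 higher, 8 lower) gave 2 and 1 with log2(summits + 0.5), 32 higher with the square root, 4 lower at a mean of at least 2, 15 lower at a mean of at least 4, 36 higher without centring, 35 higher with quantile normalization, 11 and 5 at scores of 5 or more, 5 and 2 at equal list lengths, and 38 and 14 without trend. Leaving out 1 library gave 0 to 3 higher and 0 to 1 lower. Of the 27 genes, 25 were called again without centring, 26 with quantile normalization and 5 at equal list lengths, and of the 369 refits of the 19 named genes 139 kept the call and 230 lost it. In the 213 lost refits on the reported scale the log2 fold change was 51 to 116% of that reported, with a median of 100%. The median says little about stability. The replicate block leaves the fold unchanged, and several other settings change mainly the features tested or the centring. Region coverage (15 higher, 9 lower) gave 29 and 14 with the square root, 0 lower at a mean of at least 2, 26 and 20 at a mean of at least 4, 26 and 14 without centring, 29 and 18 with quantile normalization, 7 and 3 at scores of 5 or more, 0 and 0 at equal list lengths, 8 and 1 when stitched at 5 kb and 25 higher without trend, and 0 to 2 higher and 0 lower with 1 library left out. Promoter coverage (0 and 0) gave 9 and 3 at a mean of at least 2, 3 higher without centring, 1 higher without trend and 0 to 1 higher with 1 library left out.

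Median centring gave the counts of no centring for genes (36 higher) and promoters (3 higher), as their library medians were equal, and 27 and 18 stitched regions. The planned filters on the number of libraries with a peak admit many features whose counts are equal within both groups, 43.3 to 74.7% against 4.9 to 10.6% at a mean of at least 3. A summit in at least 3 libraries gave 319 and 160 of 11779 genes, 475 and 203 of 13710 stitched regions and 0 of 10110 promoters. Of these 479 genes and 678 regions, 367 and 552 had such equal counts. The highest other split under this filter gave 38 genes and 137 regions, but 6364 promoters, so the fit cannot be relied on there. A summit in at least 1 library gave 1 and 2 genes, 4 and 0 regions and 0 promoters. A summit in all 6 gave 5 and 0 genes and 177 and 84 regions, and could not be fitted for promoters.

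The summit counts gave no sign that the replicate numbers pair the libraries, but 3 libraries per group cannot exclude it. Deviations of same-numbered libraries correlated at 0.067, 0.053 and -0.121, and not every library correlated best with its own number. With the replicate number as a block, summits per gene and region coverage gave 0 higher and 0 lower (167 and 145, and 142 and 129, at an unadjusted p under 0.05), promoter coverage and gene lists 0, and summits per library the same difference of 1397 with an exact sign-flip p of 0.25.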

Other observations

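The tests of isolated regions, of nearby summits, of the excess among high scores, of promoters of high score, of the neighbouring gene, of lists near group-specific regions and of all splits except that of the gene lists were chosen only after the result was seen. Several genes had at least 4 group-specific regions of one kind, each region assigned to its nearest start site and not always within the gene. Group-specific regions were 4.67% of all regions, and clustering at genes was not tested. MYH9, which encodes non-muscle myosin heavy chain, had 6 shSAT1-only regions and 1 shControl-only region among 35, EXT1, a heparan sulfate polymerase, had 5 and 1 of 50, and MAP4K4, a kinase, 5 and 1 of 21. FNDC3B, GREM1 and SEPTIN9 had 4 shSAT1-only regions and 0 of the other kind, while the adhesion molecule CLMP and the peptidylarginine deiminase PADI1 had 4 shControl-only regions and 0 of the other. ZFP36L1, an RNA-binding protein, had 3 and 4. These genes were chosen after their values were seen. Genes just short of the limma threshold for summits per gene included ANGPT2 (13.7 and 8.0 summits in shControl and shSAT1, adjusted p = 0.0505), HMGA2 (19.0 and 14, adjusted p = 0.0532), GLI2 (12.3 and 6.0, adjusted p = 0.0532) and TRIB1 (8.3 and 14, adjusted p = 0.0532), likewise chosen after their values were seen.

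At 53 of 8442 genes with a summit within 1 kb in all 6 libraries, the strongest such summit lay on one side of the start site in all shControl libraries and on the other side in all shSAT1 libraries, 25 of them downstream in shSAT1 and 28 upstream. They included ATF4, NR3C1, REST, STAT6, ROCK2 and JUP, the last 4 chosen after their values were seen. The other splits gave 8 to 16 such genes. A hypothesis was that SAT1 depletion may shift acetylation toward the gene body. It was not borne out: 77.4 ± 0.46% of promoter summits within 1 kb lay downstream of the start site in shControl and 76.9 ± 0.34% in shSAT1 (SD, n = 3), a difference of -0.49 percentage points with overlapping groups (exact p = 0.3).

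Regions in one group only were the first pattern weighed. Among regions whose scores lay at or above the median of all 3 lists the real split gave 198, which was 3.05 times the highest other split (65), and among isolated ones 38, which was 9.5 times the highest other split (4), so weak peaks near the score threshold do not account for all of them. Differences in copy number between the cell populations would gather the regions on some chromosomes. By Fisher's exact test 0% of them lay on a chromosome whose ratio departed from the rest (adjusted p under 0.05). The shSAT1-only share ran from 52.9% on chromosome X (18 and 16 regions) to 78.9% on chromosome 18 (30 and 8). With so few regions on some chromosomes, moderate departures could be missed. Smaller copy changes were not tested. Whether summits moved within broader peaks stays open: 42.6% of the regions, and 151 of the 198 of high score, had all 3 libraries of the other group within 3 kb, but peak widths are unknown and the other splits gave from 106 of 212 to 143 of 227 (63.0%). A difference in enrichment quality between the groups, off-target effects of the hairpin and an effect of SAT1 depletion remain open, as none of them was tested.

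The second pattern was the excess of shSAT1-only sites, by 2.15 to 1 over all regions and 2.95 to 1 over isolated ones. Longer shSAT1 lists may contribute, because equal list lengths lowered the ratio to 1.58 (95% interval 1.43 to 1.74) and to 2.0 (1.71 to 2.34) for isolated regions. These intervals cover counting error only. In the other splits the larger direction exceeded the smaller by up to 2.04 to 1 over all regions, 1.36 at equal list lengths, 7.22 over isolated regions and 2.92 over these at equal lengths, from fewer regions. Over all regions an excess of 1.58 thus remained at equal list lengths, above the other splits. The splits are too few to show that it exceeds what a grouping by chance gives. Whether list length alone accounts for the excess therefore stays open, over all regions and over isolated ones. Over all regions the ratio was 1.04 (0.79 to 1.37) among regions of high score and 2.37 (2.13 to 2.64) among the rest. This cannot decide whether peaks near the score threshold account for the excess. Of the 198 regions of high score, 151 had all 3 libraries of the other group within 3 kb. There the ratio was 0.82 (0.6 to 1.13), and a summit that lies at another position can give 1 region in each direction. Among isolated regions of high score the ratio was 2.45 (1.23 to 4.88), from 38 regions, too few to decide. An effect of the knockdown and a deeper or cleaner shSAT1 library set cannot be separated without read counts.

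The third pattern was promoters in one group only. Assignment of a summit to a neighbouring gene ended 22.8% of the 202 calls, so it accounts for a minority of them, although for 19 of the 24 named calls. Among promoters with scores at or above the median of all 3 lists the real split gave 40, which was 2.35 times the highest other split (17). Peaks near the score threshold therefore do not account for all calls by assigned gene. Only 14 of these 40 held under both definitions, and the other splits were not counted that way. Whether such peaks account for the promoters that held was thus not tested. The ratio of shSAT1-only to shControl-only promoters was 1.0 (95% interval 0.54 to 1.84) among these 40 against 2.06 over all. This cannot decide whether such peaks account for the excess of shSAT1-only promoters. Several calls of high score were pairs of neighbouring genes, with 1 gene in each direction. Among promoters that held under both definitions the ratio was 2.5 (0.83 to 7.53) at high score, from 10 against 4. It was 2.64 (1.83 to 3.81) among the other promoters that held, so the question stays open. An effect of SAT1 depletion at the 156 promoters that held is a hypothesis that may be followed at OAS3, EPAS1 and BCL2. Of these, BCL2 was a weak call, with a lowest score percentile of 16.1 against 61.5 for OAS3 and 54.5 for EPAS1.

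The 10 splits of 6 libraries are too few for a share under 0.05, so they cannot settle whether a grouping by chance gives such counts. The real split gave 1820 group-specific regions and the highest other split 478, and 202 promoters against 50; in each case 1 of the 10 splits, the real one, reached the count. The highest other split set shControl 1 and 3 with shSAT1 1 against the remaining libraries. The real split gave 27 genes for summits per gene and 24 stitched regions, with 0 in the highest other split and 1 of 10 splits reaching each count. Promoter coverage and gene lists gave 0 in the real split and 0 in the highest other split, which all 10 splits reach.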
